A study of Mus musculus with 6 samples.

How the data were processed

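RNA from mouse collecting duct cells (intermedullary in the labels, taken here as inner medullary) carrying an inducible dominant-negative HNF1B was measured on 6 one-colour Affymetrix arrays, with biotin-labelled target. HNF1B is a homeodomain transcription factor of kidney tubules and other epithelia. A dominant-negative form blocks the normal protein in the same cell. Per the labels, cells were grown for 24 h and then given an inducing compound for 48 h (72 h in all), which the labels call mifeprin, taken here to be mifepristone, or ethanol as vehicle. The 3 induced cultures are called mutant and the 3 vehicle cultures control. The labels name 1 cell line for both groups, so the compound and the induced protein cannot be told apart in this design. The titles call the replicates biological and say no more of their origin, so p-values measure the spread between these 6 arrays.

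The authors deposited log2 expression values in one table of 23308 probe sets, with a column per array. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA. In its standard form RMA corrects background, applies quantile normalization across arrays and summarises the probes of a set by median polish. Software versions, the summary level and any filter are not given in the sources used here. The values carry no detection call, so no probe set can be declared absent. Array medians lay between 7.73 and 7.76, and the values were not normalized again. The 25th percentiles differed more: 6.09, 6.04 and 6.21 in control replicates 1 to 3, and 6.25, 6.25 and 6.14 in mutant replicates 1 to 3. Small differences of dim genes can therefore reflect the arrays. With cyclic loess between arrays the mean log2 difference of endothelial markers went from 0.077 to -0.0033, and that of intercalated cell genes from 0.17 to 0.08. RMA compresses differences between dim values, so fold changes of dim genes are understated. As a yardstick chosen after the data were examined, the 1190 olfactory and vomeronasal receptor genes in the table, mostly silent outside sensory tissue, had a median level of 5.10 and a 95th percentile of 6.61. Of the 19296 genes tested, 12898 had a mean level above that percentile ("above the receptor level" below). Of the receptor genes, 37 passed the test of the main comparison.

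Probe sets were named from GEO's platform annotation. One gene symbol was given for 20728 probe sets, several for 1173, and none for 1407. Of the 20728, 20685 matched a current gene entry by Entrez identifier, and no symbol needed updating. Genes with more than 1 probe set (804) were represented by the probe set with the highest mean over the 6 arrays, and for none of them did probe sets change in opposite directions. Probe sets with several or no symbols stayed out of the main test. No probe set used here is named Hnf1b or Hnf1a, so the targeted gene was not analysed here and the labels could not be checked against it. No genome coordinates are given because the array's genome build is not given in the sources used here.

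Mutant was compared with control by limma 3.58.1 (lmFit and eBayes, R 4.3.3) with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over the 19296 genes. A gene was called changed at an adjusted p under 0.05, and a second count asked in addition for at least a 2-fold change. Group values are means ± SD of the log2 values of 3 arrays, and fold changes carry the standard error of the fit. Adjusted p-values for genes are from limma throughout. Before the data were examined, 24 lists of pathway genes and cell type markers were fixed, with 329 entries, of which 306 were measured. The lists on HNF1B were drawn from published work that includes this kind of cell line and could include these arrays, so their direction is not independent evidence. Lists were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the 24 lists, with camera at an estimated correlation and fry beside it. Camera compares the genes of a list with all other genes. Fry's directional p asks whether the genes of a list move on balance one way.

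The genes named were chosen by a rule fixed in advance. It takes the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05 and no overlap between the 2 groups, leaving out predicted, clone-named, small RNA and receptor genes. It adds the 5 members of each list with the smallest p, and Hnf1b and Hnf1a, which have no values here. Genes named outside the rule are marked as chosen after their values were seen.

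The fit was tested on simulated data with the real genes' means and spreads. Of 67 genes given a log2 change of 0.5, 49.3% were called in the right direction. The share was 89.6% of 67 genes at a change of 1 and 100% of 66 genes at a change of 2. There were 5 false calls among 174. The real data gave 3218 calls, so the adjusted threshold was stricter in p in the simulation, and these shares are not those of the real data. A list shifted by -0.4 was called, and it was the only 1 of the lists called. The simulated genes were drawn independently, so this does not test list calls where genes vary together. In the real data the HNF1B target, cholesterol and cilium lists had estimated correlations of 0.15, 0.18 and 0.54.

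Alternatives fixed in advance were quantile normalization and median centring of the deposited values, 2 filters on dim genes, a trended robust prior, array weights, the replicate number as a block, leaving out each array, averaging a gene's probe sets, testing all probe sets, a test against a minimum fold of 1.5, camera with an estimated correlation, and fry. Cyclic loess between arrays, and leaving out control replicate 3 and mutant replicate 3 together, were added after the data were examined. A count within 1.5 times the main one was taken as unchanged. A gene or list that passes the test neither as reported nor in the alternative has no called direction, and a change of its sign was not counted as a reversal. Deviations from the group means of arrays with the same replicate number correlated at 0.13, -0.06 and -0.15 over genes. No pairing by number thus showed over all genes together, but this does not exclude one in part of the genes. Several of the genes most variable within groups, named after their values were seen, followed the number in both groups. Egr1, Ccn1, Ccn2, Fosl1, Dusp5, Dusp6, Nr4a1 and Ccl2 fell from replicate 1 to replicate 3, and Cldn8 and Ankrd37 rose. Others, such as Bnip3 and Prp2, did not keep the same order in both groups. Upk1a, named after its values were seen, was 8.88, 9.23 and 9.83 in control and 8.82, 9.23 and 9.81 in mutant cells. Whether the numbers pair the samples is not known, and the main fit did not pair them. The number of arrays limits the precision of every value.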

Results

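Gene expression was measured in 6 cultures of a mouse inner medullary collecting duct cell line, an epithelial line from the last part of the kidney tubule. In 3 of them a dominant-negative form of the transcription factor HNF1B had been induced for 48 h, and the other 3 had received vehicle. The single comparison, induced (mutant) against vehicle (control), asks which transcripts change when HNF1B function is blocked. Expression values are log2 RMA levels, and each group value below is a mean ± SD with n = 3. Arrays of one group correlated at 0.995 to 0.998 over genes, and arrays of different groups at 0.986 to 0.989. The first principal component held 68.9% of the variance and separated the groups. The second held 12.8% and set mutant replicate 3 (score 17.1) against the other mutant arrays (-7.12 and -7.02), with control replicate 3 (-10.9) apart from the other controls.

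Of 19296 genes, 3218 (16.7%) changed, 1460 of them higher and 1758 lower in mutant cells (limma, adjusted p under 0.05). At least 2-fold changes were found for 167 genes that rose and 189 that fell. The 3 arrays of each group did not overlap for 35.9% of genes, against 10% by chance. The median gene differed by 0.03 on the log2 scale. The count of 3218 depended on single arrays: it was 2006 without control replicate 2, 2042 without mutant replicate 1 and 1965 without mutant replicate 2. It was 7089 without replicate 3 of both groups. The arrays kept in that fit had 25th percentiles of 6.09 and 6.04 in control and 6.25 and 6.25 in mutant cells. Rises of dim genes in that fit, here and below, cannot be told apart from this shift between arrays. The count of at least 2-fold changes stayed between 345 and 361 when any 1 array was left out.

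The largest fall was in Scnn1g, the gamma subunit of the epithelial sodium channel, which went from 11.02 ± 0.33 in control to 6.77 ± 0.46 in mutant cells, 19.0-fold lower (log2 fold change -4.25, SE 0.24, adjusted p = 2.96e-05). Tspan8, a tetraspanin, was 15.6-fold lower and Cbs, cystathionine beta-synthase of homocysteine metabolism, 11.4-fold lower. G6pc2, a glucose-6-phosphatase subunit, fell 7.44-fold and the cadherin Cdh6 fell 7.20-fold. Aldh1a2, which makes retinoic acid, fell 6.85-fold, and Jag1, a Notch ligand, fell 6.81-fold from 11.77 ± 0.05 (log2 fold change -2.77, SE 0.06, adjusted p = 6.57e-07). Ntm (6.80-fold), the sulfotransferase Sult1c2 (6.75-fold), the kinase Cdkl1 (6.23-fold), the methyltransferase Inmt (6.07-fold) and Cldn2, a pore-forming claudin (5.70-fold), completed the 12 largest falls. Mutant levels of Tspan8 (6.20 ± 0.33) and G6pc2 (6.38 ± 0.30) lay below the 95th percentile of receptor genes (6.61), and that of Scnn1g lay just above it. RMA compresses differences at such levels.

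The largest rise was in Gstm7, a glutathione S-transferase of the mu family, from 8.18 ± 0.24 to 12.12 ± 0.14, 15.3-fold higher (log2 fold change 3.94, SE 0.13, adjusted p = 3.80e-06). The family has near-identical members, so its value is uncertain. Tmem64 rose 8.22-fold (adjusted p = 6.57e-07) and Prune2 7.66-fold. Slpi, a secreted protease inhibitor, rose 6.26-fold, and Lcn2, the siderophore-binding lipocalin used as a marker of kidney injury, rose 4.93-fold (9.10 ± 0.13 to 11.40 ± 0.02). Fzd4, a Wnt and Norrin receptor, rose 5.75-fold. Dcn, the matrix proteoglycan decorin, rose 5.33-fold from 5.78 ± 0.10, within the range of receptor genes, to 8.19 ± 0.54. The Golgi mannosidase Man2a2 (5.26-fold), Mab21l4 (4.86-fold), Klhdc8a (4.85-fold), Psca (4.65-fold) and the zinc exporter Slc30a1 (4.55-fold) were the remaining members of the 12 largest rises.

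**Figure D1:**
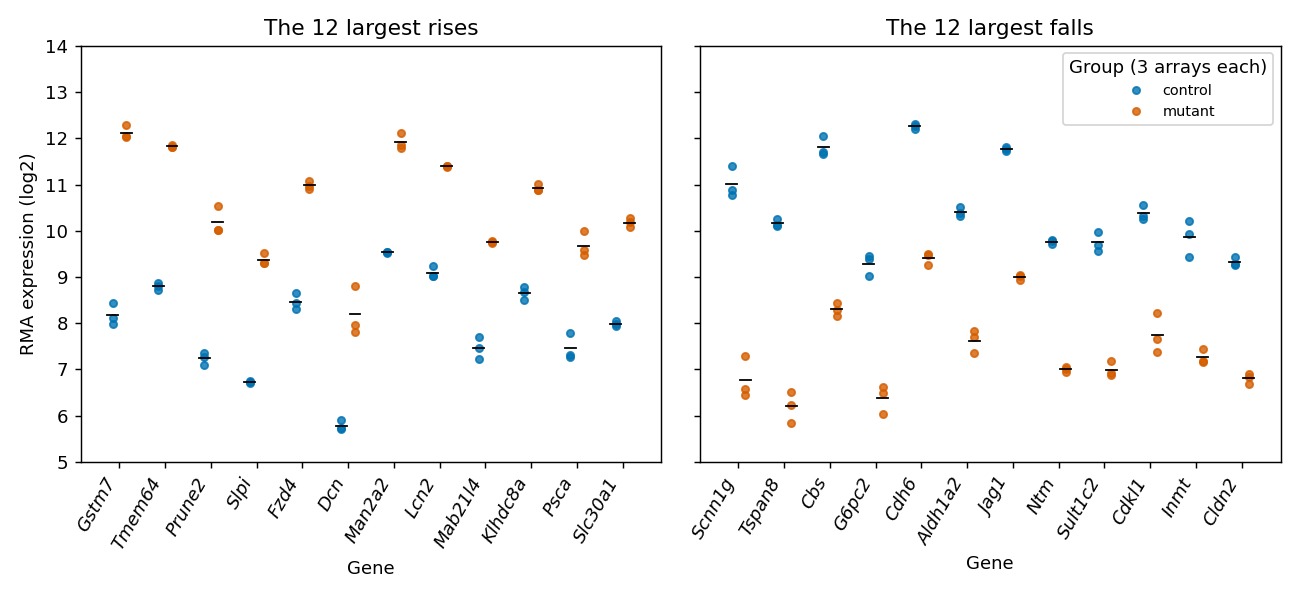
Log2 RMA expression (vertical axis) of the 12 genes with the largest rise and the 12 with the largest fall in mutant cells (horizontal axis), with 1 point per array, control in blue, mutant in orange, and a bar at each group's mean. For each of the 24 genes the 3 mutant arrays lie clear of the 3 control arrays, with Gstm7 15.3-fold higher and Scnn1g 19.0-fold lower.

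Genes reported as activated by HNF1B were mostly lower in mutant cells. Of 13 measured members, 9 fell, 1 rose and 3 did not pass. The list comes from published work that could include these cells, so this is not independent evidence of its direction. Pkhd1, the gene of autosomal recessive polycystic kidney disease, fell from 10.12 ± 0.07 to 7.83 ± 0.13, 4.89-fold (log2 fold change -2.29, SE 0.08, adjusted p = 3.88e-06). The kinesin Kif12 fell 3.45-fold, Cys1, which encodes the ciliary protein cystin, 3.40-fold, and Cdh16, kidney-specific cadherin, 3.13-fold. Bicc1, an RNA-binding protein whose loss gives renal cysts, fell 2.03-fold. The member that rose, named after its value was seen, was Nr1h4, the bile acid receptor FXR, by 0.42 on the log2 scale (SE 0.11, adjusted p = 0.032). Adjusted over the list alone, 9 fell and 2 rose. The list was lower by camera (adjusted p = 5.25e-08). With an estimated correlation the adjusted p = 0.318. Among 4 genes reported as repressed by HNF1B, Lef1 (log2 fold change 2.01, SE 0.13) and Socs3 (1.14, SE 0.10) rose, Twist2 fell (-0.88, SE 0.10) and Snai2 did not pass (0.02, SE 0.09). Adjusted over the list alone, the counts were also 2 and 1, and camera did not call the list (adjusted p = 0.552). Fry called those 4 genes higher (adjusted p = 0.0159). The 4 measured loci of the miR-200 family, which HNF1B has been reported to control, did not pass, and 1 of them lay above the receptor level. Their differences ran from -0.15 (SE 0.18) for Mir200b to 0.33 (SE 0.20) for Mir200c, and none passed over the list alone (camera adjusted p = 0.891). Mir200c passed without control replicate 3 (0.55, adjusted p = 0.0454), and without replicate 3 of both groups Mir200c (0.68, adjusted p = 0.00854) and Mir141 (0.32, adjusted p = 0.0148) rose. Both also passed with array weights (adjusted p = 0.0165 and 0.0174), with ranges up to 0.647 and 0.531 over the alternatives. Mir200c and Mir141 lay below the receptor level by their means, where shifts between arrays matter most. The mean of the miR-200 list was 0.08 as reported and -0.0006 with cyclic loess.

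Genes of cholesterol synthesis and its regulation were lower as a group. Of 20 measured, 14 fell and 1 rose, and 5 did not pass (15 and 1 adjusted over the list alone). The uptake genes of the list, Ldlr and Pcsk9, and the synthesis genes Hmgcr, Dhcr24 and Acat2 were not analysed here. Hmgcs1, the synthase that feeds the mevalonate pathway, fell 2.39-fold (11.98 ± 0.12 to 10.73 ± 0.09, adjusted p = 5.22e-05). Cyp51 fell 1.90-fold, Lss 1.73-fold, Msmo1 1.70-fold and Idi1 1.62-fold, all enzymes of the same pathway. The member that rose was Stard4, an intracellular sterol carrier named after its value was seen (log2 fold change 0.30, SE 0.08, adjusted p = 0.036). Camera called the list (adjusted p = 7.73e-10), and with an estimated correlation the adjusted p = 0.318. Genes of fatty acid synthesis did not shift as a group (median 0.03, mean -0.05, camera adjusted p = 0.834). Of 12, 2 fell, Elovl6 (log2 fold change -0.69, SE 0.06) and Acly (-0.35, SE 0.07), and 10 did not pass, with the same counts over the list alone. Srebf1, the regulator of this pathway, differed by 0.17 (SE 0.07, adjusted p = 0.127), and passed with cyclic loess (0.22, adjusted p = 0.0411) and with array weights (0.16, adjusted p = 0.0407), with a range up to 0.322.

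Cilium and polycystic kidney disease genes were also lower. Of 18 measured, 13 fell, 1 rose and 4 did not pass, with the same counts adjusted over the list alone. Cc2d2a and Rpgrip1l, of the ciliary transition zone, fell 2.07-fold (adjusted p = 4.46e-04) and 1.64-fold, and Ift88, of intraflagellar transport, fell 1.55-fold. Pkd1, the main gene of dominant polycystic kidney disease, was the member that rose, from 9.09 ± 0.05 to 9.70 ± 0.10 (1.53-fold, adjusted p = 9.54e-04). Pkhd1 and Ift88 are in this list and in the list of HNF1B targets. Camera called the list (adjusted p = 1.79e-07), and with an estimated correlation the adjusted p = 0.934.

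Genes of the principal cells of the collecting duct did not move together by camera, but fry called the list lower (adjusted p = 0.0159). Of 14 measured, 3 fell, 1 rose and 10 did not pass (the same over the list alone), and 9 lay above the receptor level. Beside Scnn1g, the urea transporter gene Slc14a2 fell 3.27-fold (8.81 ± 0.12 to 7.10 ± 0.08, adjusted p = 1.60e-05) and the transcription factor Tfcp2l1 fell 1.80-fold. Of the other sodium channel subunits, Scnn1a rose by 0.71 on the log2 scale (SE 0.15, adjusted p = 0.015), and Scnn1b had a log2 fold change of -0.32 (SE 0.12, adjusted p = 0.122), at levels below the receptor level. Scnn1b passed with a further quantile normalization (-0.41, adjusted p = 0.0190), with cyclic loess (-0.41, adjusted p = 0.0197) and without mutant replicate 1 (-0.44, adjusted p = 0.0396), with a range up to 0.339. The call for Scnn1a was lost without control replicate 2 (adjusted p = 0.0506, with a range of 0.00395 to 0.0767 over the alternatives). The list's median was 0.07, its mean was -0.39, carried by Scnn1g, and camera gave an adjusted p of 0.728. With genes under the median brightness left out, camera called the list lower (adjusted p = 0.0184, with a range up to 0.893), and without replicate 3 of both groups 3 members rose and 3 fell. Of 10 intercalated cell genes, Slc26a4, the anion exchanger pendrin, rose (log2 fold change 0.76, SE 0.14, adjusted p = 0.0082) and 9 did not pass, also over the list alone (camera adjusted p = 0.283). Only 4 of the 10 lay above the receptor level by their mean, and Slc26a4 was not among them. Without replicate 3 of both groups, 5 of the 10 rose and 1 fell, and Aqp6 (log2 fold change 0.36, SE 0.11, adjusted p = 0.0568) passed in 6 of 15 alternatives, with a range of 0.00523 to 0.181.

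The osmotic stress list split. Of 9 measured, 4 rose, 2 fell and 3 did not pass (4 and 3 over the list alone). The myo-inositol transporter Slc5a3 rose 2.39-fold, Nfat5, the transcription factor of the hypertonic response, rose 1.32-fold and Hspa1a rose 1.30-fold. Slc14a2 and the taurine transporter Slc6a6 (1.48-fold) fell. The call for Nfat5 (adjusted p = 0.0118) was lost without control replicate 2, where the adjusted p was 0.0500083, with a range from 6.48e-04 over the alternatives. The list's median was 0.17 and its mean -0.0019, and camera gave an adjusted p of 0.891.

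Mesenchymal genes were not raised as a group. Of 19 measured, 5 fell, 1 rose and 13 did not pass, also over the list alone (median 0.04, mean -0.15, camera adjusted p = 0.728). Vim, the intermediate filament vimentin, fell 2.13-fold (11.71 ± 0.24 to 10.62 ± 0.29, adjusted p = 0.0030). The transcription factors Zeb1 (1.90-fold) and Twist2 (1.84-fold), the matrix protein Postn (1.88-fold) and the N-cadherin gene Cdh2 (1.49-fold) fell too, with Postn below the receptor level in both groups. The member that rose, named after its value was seen, was Zeb2 (log2 fold change 0.49, SE 0.12, adjusted p = 0.024). Without replicate 3 of both groups, 5 of the 19 rose and 5 fell. Cdh2 lost its call when control replicate 1, control replicate 2 or mutant replicate 1 was left out (adjusted p = 0.0610, 0.0647 and 0.0501, with a range from 0.00367 over the alternatives). Of 21 epithelial junction and keratin genes, 6 rose, 5 fell and 10 did not pass (9 and 5 over the list alone, camera adjusted p = 0.834). Rab25 (1.81-fold) and Ovol1 (1.71-fold) were among those that rose, and the splicing regulator Esrp1 (1.49-fold) and the tight junction gene Ocln (1.48-fold) among those that fell.

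Among 13 genes of the TGF-beta and BMP response, 3 rose, 3 fell and 7 did not pass, also over the list alone (median 0.15, mean -0.10, camera adjusted p = 0.948). Id3 rose 1.73-fold and Id2 1.25-fold, whereas Tgfb1 fell 1.69-fold and Smad7 1.75-fold. Tgfbi also rose (log2 fold change 0.33, SE 0.08, adjusted p = 0.0276). It passed in 11 of 15 alternatives, with a range of 0.00635 to 0.101. Of 13 genes of the Wnt/beta-catenin response, 2 rose, 2 fell and 9 did not pass, also over the list alone (median -0.0035, mean 0.11, camera adjusted p = 0.895). Lef1, a transcription factor and target of the pathway, rose 4.02-fold (7.59 ± 0.21 to 9.60 ± 0.19, adjusted p = 4.59e-05) and Axin2 rose 1.57-fold. Znrf3, which removes Wnt receptors from the cell surface, fell 1.71-fold and Apcdd1 fell 1.34-fold. Apcdd1 lost its call without control replicate 2 (adjusted p = 0.0641) or mutant replicate 1 (adjusted p = 0.0679), with a range from 0.00673 over the alternatives. Without replicate 3 of both groups, 5 of the 13 rose and 2 fell.

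**Figure D2:**
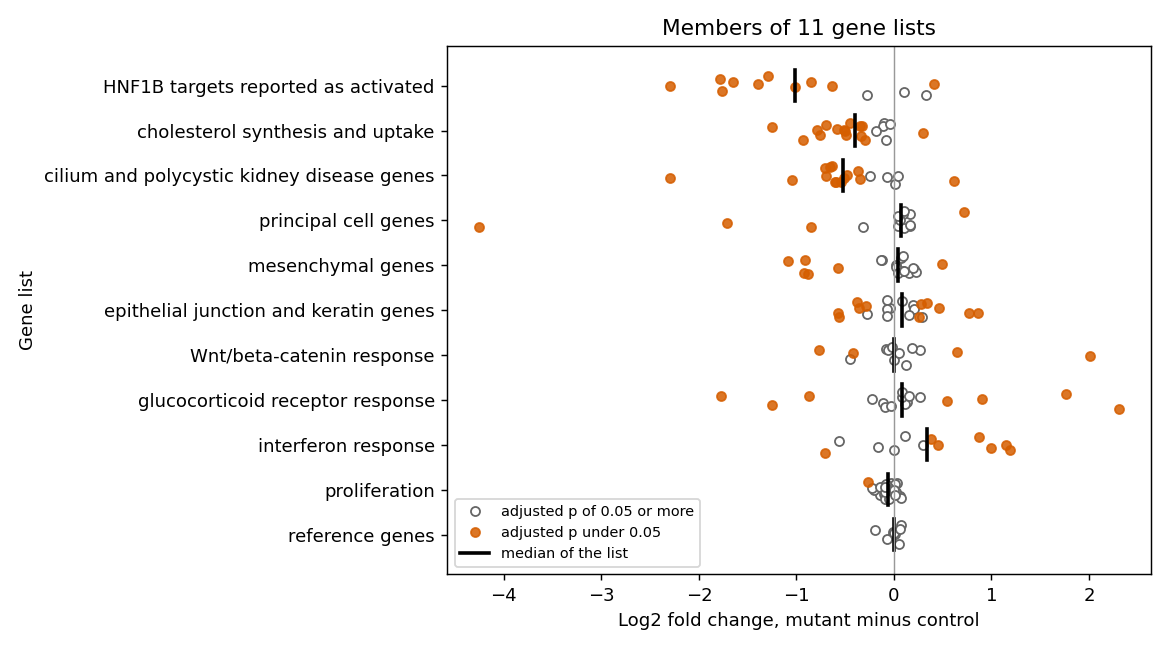
Log2 fold change, mutant minus control (horizontal axis), of the measured members of 11 gene lists (vertical axis), with 1 point per gene, filled where the limma adjusted p is under 0.05, and a black bar at each list's median. The HNF1B target, cholesterol and cilium lists have medians of -1.02, -0.40 and -0.53, and the reference genes lie close to 0.

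Glucocorticoid-responsive genes were examined because mifepristone, which the inducing compound is taken to be, also blocks the glucocorticoid receptor. Of 17, 4 rose, 3 fell and 10 did not pass, also over the list alone (camera adjusted p = 0.834). Fry called the list higher (adjusted p = 0.0236). Lcn2 and Nfkbia, the NF-kappaB inhibitor (3.39-fold), were among those that rose. The metallothioneins Mt2 (3.42-fold) and Mt1 (1.83-fold) and glutamine synthetase Glul (2.38-fold) fell. Of 14 xenobiotic response genes, 3 rose, 2 fell and 9 did not pass (3 and 3 over the list alone, median 0.04, mean -0.0080, camera adjusted p = 0.965). Ephx1 rose 1.47-fold and Gsta4 fell 1.81-fold. The calls of Cyp1a1, below the receptor level in both groups, and Abcb1b, which rose, and of Cyp1b1, which fell, were all lost without control replicate 2 (adjusted p = 0.0709, 0.0946 and 0.111), without mutant replicate 1 (0.0707, 0.113 and 0.0597) and without mutant replicate 2 (0.0565, 0.0973 and 0.0903), with a lowest value of 0.0025 over the alternatives.

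Interferon-responsive genes had 6 of 12 members that rose, 1 that fell and 5 that did not pass, also over the list alone. Ifit1 rose 2.27-fold, Oasl2 2.00-fold, Usp18 1.83-fold and Irf7 1.30-fold, while Ifit3 fell from 12.97 ± 0.05 to 12.27 ± 0.19, 1.63-fold. Ifit3 has a near-identical neighbour, so its value is uncertain. Camera did not call the list (adjusted p = 0.114), but called it without control replicate 1 (adjusted p = 0.0414) and without mutant replicate 2 (adjusted p = 0.0358), with a range up to 0.588 over the alternatives. Fry called the interferon list higher (adjusted p = 0.0290). In this list 6 members rose and 2 fell without replicate 3 of both groups. Of 15 genes of the unfolded protein and integrated stress responses, 2 rose, 1 fell and 12 did not pass, also over the list alone (median -0.07, mean 0.02, camera adjusted p = 0.728). Those were Atf3 (log2 fold change 0.98, SE 0.25), Ddit3 (0.31, SE 0.07) and Herpud1 (-0.43, SE 0.08). The calls of Atf3 and Ddit3 were each lost when control replicate 2, mutant replicate 1 or mutant replicate 2 was left out, and that of Atf3 with a trended robust prior (adjusted p = 0.0817), with adjusted p between 0.0618 and 0.109, against a lowest value of 0.00288 over the alternatives. Of the 15, 3 rose and 2 fell without replicate 3 of both groups.

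Most proliferation genes did not pass. Of 27 measured, 26 did not pass, and Bub1b, of the spindle checkpoint, fell by 0.27 on the log2 scale (SE 0.06, adjusted p = 0.025). That call was lost over the list alone and, with an adjusted p between 0.0556 and 0.104, in 5 of the 6 fits with 1 array left out. Mki67 and Top2a had log2 fold changes of -0.15 (SE 0.08) and -0.21 (SE 0.07), and Tyms one of -0.22 (SE 0.07). Top2a passed in 5 of 16 alternatives (adjusted p from 0.0131 to 0.293) and Tyms in 6 of 16 (0.00858 to 0.216). Camera gave an adjusted p of 0.114 for the list (mean -0.07). It called the list in 4 of 16 alternatives, among them without control replicate 1 (adjusted p = 0.0449) and without replicate 3 of both groups (0.0410, where 4 members fell), with a range up to 0.543. None of 9 reference genes passed, also over the list alone (median 0.0033, mean -0.01, camera adjusted p = 0.891). Their differences ran from -0.19 (SE 0.06) for B2m to 0.07 (SE 0.06) for Tbp, and B2m passed in 3 of 16 alternatives, with a lowest adjusted p of 0.00505.

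Markers of other kidney and stromal cells gave no shared shift by camera. Fry called the proximal tubule list lower (adjusted p = 0.0163) and the fibroblast list higher (adjusted p = 0.0290). Of 11 proximal tubule genes, the water channel Aqp1 (3.16-fold) and the endocytic receptor Lrp2 (2.49-fold) fell, Miox rose (log2 fold change 0.24, SE 0.07, adjusted p = 0.049) and 8 did not pass, also over the list alone (median 0.08, mean -0.19, camera adjusted p = 0.834). Miox lay below the receptor level in both groups and passed in 5 of 14 alternatives, with an adjusted p up to 0.166. Without replicate 3 of both groups, 5 of the 11 proximal tubule genes rose and 2 fell. None of 7 loop of Henle genes (camera adjusted p = 0.891) and none of 8 endothelial genes (0.728) passed, also over each list alone, but without replicate 3 of both groups 2 loop genes rose, and 2 endothelial genes rose and 1 fell. Of 8 fibroblast genes, Dcn rose and 7 did not pass, also over the list alone (camera adjusted p = 0.114). Without replicate 3 of both groups 5 of the 8 passed upward, and camera called the list (mean 0.52, adjusted p = 0.0213, with a range up to 0.237 over the alternatives). The highest value was with cyclic loess (mean 0.38). Of 8 leukocyte genes, Cd68 rose (log2 fold change 1.00, SE 0.17), Csf1r fell (-0.77, SE 0.09) and 6 did not pass, also over the list alone (camera adjusted p = 0.747). Those 6 lay below the receptor level, and without replicate 3 of both groups 3 of the 8 rose and 1 fell. Rises of dim markers in the fit without replicate 3 cannot be told apart from the shift between the arrays kept.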

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

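Probe sets outside the main comparison also changed. Of 1173 probe sets that the annotation gives to several genes, 91 passed the test over all probe sets (limma, adjusted p under 0.05), 43 higher and 48 lower in mutant cells, or 7.76%. Of 1407 probe sets without a gene name, 143 passed, 64 higher and 79 lower, or 10.2%. Both shares lie below the 16.7% of genes that passed in the main comparison. These probe sets were singled out because their signal lies in data that the comparison above does not use. The largest rises were in probe sets 10363541 (log2 fold change 3.81, SE 0.32, adjusted p = 3.00e-04) and 10471154 (3.73, SE 0.14), each shared by several genes. The largest falls were in probe sets 10562592 (-2.32, SE 0.09) and 10569335 (-2.23, SE 0.12), which have no gene name here. Single outlying samples were not tested for in groups of 3 arrays.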

How the results depend on the processing

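Cyclic loess and the omission of replicate 3 from both groups were chosen after the data were seen. The count of 3218 changed genes (1460 higher, 1758 lower) was 8207 (4860 and 3347) with array weights, 7089 (4308 and 2781) without control and mutant replicate 3, and 309 (146 and 163) in the test against a minimum fold of 1.5, which asks for larger changes by construction. The share of changed genes that were higher was 45.4% as reported, 59.2% with array weights and 60.8% without replicate 3. Leaving out 1 array gave 1965 to 4500 genes, 887 to 2179 higher and 1035 to 2321 lower, and 3 to 5 gene lists. With the replicate number as a block the count was 2454, of which 2320 were among the 3218, and the 3 called lists were again 3 lists. The block leaves every log2 fold change as it was, and whether the numbers pair the samples is not known. Among named genes, the calls of Scnn1a (adjusted p = 0.0767), Abcb1b (0.0741), Miox (0.0790) and Tjp1 (0.0512) were lost with the block. The 3 lists called by camera became 5 without replicate 3 of both groups, 9 with fry, whose test does not compare a list with other genes, and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05. Besides those 3, fry called the HNF1B-repressed (adjusted p = 0.0159), glucocorticoid (0.0236), interferon (0.0290) and fibroblast lists (0.0290) higher. It called the principal cell (0.0159) and proximal tubule lists (0.0163) lower. For the moves with array weights and without replicate 3 the cause was not tested. Without replicate 3 of both groups, the arrays kept had 25th percentiles of 6.09 and 6.04 in control and 6.25 and 6.25 in mutant cells. Rises of dim genes in that fit therefore cannot be told apart from a shift between arrays. All other alternatives gave between 3217 and 3894 genes and 3 or 4 lists. For single named genes and lists, 2339 of 2481 recomputed values kept their side of the threshold and direction, 53 lost a call, 89 gained one and 0 reversed. The HNF1B level could not be recomputed because no probe set used here bears that name. With 3 arrays per group, 49.3% of simulated changes of 0.5 on the log2 scale were recovered. Far fewer genes changed in the simulation, which made its cut-off in p stricter. How often changes of that size are missed in the real data was not measured.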

Other observations

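Several gene groups outside the lists fixed at first were examined with 5 further lists, written after the main results were seen but before their own values were. The members of these lists given below, and all other genes in this part that the naming rule does not take, were named after their values were seen. The tests of Ptprc and of 4 glucocorticoid-responsive genes below were chosen after the result was seen. Hedgehog pathway genes did not shift together (10 measured, 1 rose, 2 fell, 2 and 2 without replicate 3 of both groups, camera adjusted p = 0.567 over the 5 lists). Gli3 rose (log2 fold change 0.90, SE 0.10, adjusted p = 7.02e-04), whereas the receptor Ptch1 (-0.64, SE 0.10) and the transducer Smo (-0.34, SE 0.07) fell. In zinc handling, the exporter Slc30a1 rose by 2.19 and the importer Slc39a10 by 0.63 (SE 0.06, adjusted p = 3.36e-04) while Mt1 and Mt2 fell (log2 fold change -0.87 and -1.77). Slc30a1 and the metallothioneins are textbook targets of the same zinc-sensing factor, MTF1, and moved in opposite directions here.

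In the interferon group, Ifit3 and its near-identical neighbour Ifit3b (log2 fold change -1.96, SE 0.26, adjusted p = 0.0018) fell while Ifit1, Oasl2 and Usp18 rose. One control value stood far off: Orai2 was 4.83 in control replicate 1 and 9.60 and 8.73 in the other controls, against 9.50 to 9.86 in mutant cells. Egr1 was 9.13 in control replicate 3 against 10.74 and 10.66 in the other controls, and 9.69 in mutant replicate 3 against 10.66 and 10.55. Ccn2 was 10.99 in control replicate 3 against 12.07 and 11.56, and 10.13 in mutant replicate 3 against 11.43 and 11.06.

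The fall of cilium genes extended beyond the first list. Of 39 further cilium genes, none shared with that list, 20 fell and 0 rose (23 and 1 adjusted over the list alone), with a median of -0.33, and camera called them (adjusted p = 3.09e-09, but 0.542 with an estimated correlation). Ift57 (log2 fold change -0.88, SE 0.12), Wdr35 (-0.76, SE 0.10) and Ift81 (-0.74, SE 0.12) fell most. A shift between arrays that depends on brightness is argued against. After cyclic loess the first list's median was -0.50, below the 2.5th percentile (-0.15) of 10000 lists matched on brightness, and 13 members fell. A lower yield of transcripts of large coiled-coil proteins is argued against as the whole cause by 32 centrosome and gamma-tubulin genes, whose median was -0.10 (3 rose, 3 fell, with 4 and 5 over the list alone and 3 and 7 without replicate 3 of both groups). Camera called that list lower too (adjusted p = 0.0289, but 0.542 with an estimated correlation), so a small part of the fall stays open to it. The means of the first cilium list and the centrosome list differed by -0.43 (permutation test over genes, which are not independent replicates, two-sided p = 3.60e-04). An effect of blocked HNF1B on cilium genes stays a hypothesis, and an effect of the inducing compound, or of growth state on ciliation, was not tested.

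Inflammatory genes (Lcn2, Slpi, Nfkbia) were among the large rises. Ccl2 (log2 fold change 1.96, SE 0.34), Lta (1.67, SE 0.10) and Tlr1 (1.63, SE 0.20) rose too. An NF-kappaB response list without those genes had 6 of 25 members that rose and 0 that fell (9 and 1 over the list alone), led by Saa3 (0.93, SE 0.13), below the receptor level in both groups, and Ccl7 (0.81, SE 0.14), with a median of 0.20. Camera called it (adjusted p = 0.0018), but not with an estimated correlation (adjusted p = 0.542), and 17 of the 25 lay above the receptor level, so a mild NF-kappaB response is consistent with the data and no more. The labels name 1 cell line in culture and no leukocytes, so the design gives leukocyte RNA no known source. The marker values alone do not decide it. Ptprc differed by -0.046 (SE 0.079), but the mean levels of Ptprc, Lyz2 and C1qa lay below the receptor level, so that they exclude nothing, and of the brighter markers Cd68 rose (1.00, SE 0.17, adjusted p = 0.0059) and Csf1r fell (-0.77, SE 0.09) from levels already high in control cells. Loss of glucocorticoid receptor activity from the inducing compound, which could release inflammatory genes, cannot be told apart from an effect of HNF1B. Cells given the compound without the construct were not analysed here. Fkbp5, Tsc22d3, Per1 and Zbtb16 had a median of 0.0031 and none passed. In the fixed list of 17 glucocorticoid-responsive genes, 3 fell, Mt2 (-1.77), Glul (-1.25) and Mt1 (-0.87), and 4 rose, Lcn2 and Nfkbia among them. These values do not decide the question.

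Jag1 and Hey2 (log2 fold change -1.71, SE 0.09) were among the large falls, which raised the hypothesis that Notch pathway genes were lower as a set. The remaining 19 genes of the Notch list argue against a fall across the pathway: their median was 0.077, 5 rose and 3 fell (5 and 4 over the list alone, 6 and 5 without replicate 3 of both groups), and camera did not call the list (adjusted p = 0.386, 0.542 with an estimated correlation). Fry called the list higher (adjusted p = 0.00196). Notch1 (-1.08, SE 0.09) and Nrarp (-0.61, SE 0.07) fell, while Hey1 (1.28, SE 0.07) and Dll1 (1.08, SE 0.07) rose. Whether Notch signalling itself differed was not tested.

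The 6 arrays can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split was the 1 split of the 10 with as many as 3218 changed genes, and the highest count of the other splits was 0. For lists called by camera at its preset correlation, 6 of the 10 splits gave at least the 3 of the real split, and the highest other count was 6. Of the 9 other splits, 2 called the HNF1B target list, 7 the cholesterol list and 4 the cilium list. The largest medians of these lists in the other splits were 0.36, 0.15 and 0.32 in size. In the real split they were 1.02, 0.40 and 0.53. Every other split sets 2 arrays of one group and 1 of the other against the rest, so it keeps part of the real difference and is no clean measure of how camera behaves without one. Splits that called 4 or 6 lists included some that the real split does not call, with 0 changed genes. List calls by camera at its preset correlation therefore call for caution.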
